A study of Bos taurus with 4 samples.

How the data were processed

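The study measured small RNAs of bovine oocytes at the germinal vesicle stage by sequencing, in 2 input libraries and 2 libraries of RNA co-precipitated with an anti-Tdrkh antibody. Per the labels, RNA was extracted with TRIZOL, libraries were made with the NEXTflex Small RNA-Seq Kit V3 and sequenced single-end on a NextSeq 500. The deposited files list, for each library, sequences with their read counts and the names that the unitas annotation tool gave them, and the sums of the listed counts differ between libraries. The aligner settings of that annotation and the genome build of its piRNA cluster coordinates are not given in the sources used here. Every listed sequence was of 18 to 36 nt and had a name, so reads without annotation were not analysed here and all totals are of annotated reads.

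The 4 libraries were grouped by their labels. Input 1 held 1079364 listed reads and 336526 distinct sequences, input 2 1354003 and 377640, TDRKH IP 1 11138905 and 1328333, and TDRKH IP 2 11060320 and 1354763. At these depths the Wilson 95% interval of a share was narrow (82.3% to 82.5% for reads of input 1 that begin with T), and 3 counts over the group, the floor used for names with no reads, correspond to 1.23 RPM over the inputs and 0.135 RPM over the IPs. Counts include PCR copies.

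Each name of the files was a feature, and a sequence with several names was divided equally among them, with sums rounded. A name given as having no reads may therefore still hold a fraction of a shared read that rounding removed. The 38611 names were filtered with edgeR's filterByExpr, which kept 5414. Sequences were kept with at least 10 RPM in 2 libraries, and read lengths with at least 1000 reads. TDRKH IP was compared with input by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) for names, sequences, read lengths and RNA classes, with the total of listed reads as library size and no further factor. All adjusted p are Benjamini-Hochberg values, with a threshold of 0.05. The standard error of a log2 change was approximated from the change and the F statistic. Lists of microRNA families and marker microRNAs, tRNA types, snRNAs, snoRNA, rRNAs and other structural RNAs were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, where at least 3 members were measured; members were also counted by the edgeR test over all names and adjusted over the list alone. Within lists microRNA arms were summed, since the annotation gives arm names to inexact matches too. Shares of reads by first base, base at position 10 and length were compared as mean and SD with the exact permutation test of 2 against 2 libraries, whose smallest possible p is 0.333. An added 3′ base was counted where a sequence equalled a more abundant sequence of the same library plus 1 base. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

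Named features were, in each direction, the 10 with the most reads in the higher group and the 5 further ones with the largest log2 change, among those past the threshold with both IPs on the same side of both inputs. Named sequences were the 5 with the most reads in each group, of which 3 are named and the others are not reported here, for a reason other than their values, and for lists the members with the most reads. The lists, tests, this rule and the first set of alternatives were fixed before the data were examined.

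Those alternatives were TMM factors, DESeq2 1.42.0 with its own size factors or totals, total microRNA reads as library size, other filters, sequences with a single name only, reads of 18 to 32 nt, each distinct sequence counted once, sequences seen more than once, leaving out the 10 most abundant sequences, the replicate number as a block, an estimated correlation, and leaving out each library in turn. Where a library was left out, the lone library of a group was assumed to vary like the other group. Alternatives added after the data were seen were piRNA cluster reads as library size, merged names of 1 locus or family, IPs thinned to 1079364 reads, piRNA cluster reads only, the last base against longer reads, and microRNA names exactly as listed. For that last base, longer reads of all libraries were pooled. A position counted where at least 5 of them covered it and 90% of these had the same base.

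The tests were tested on simulated data with 200 changed items each. With the mean of the libraries as baseline, edgeR recovered 7 of 60 names changed 1.5-fold, 31 of 73 changed 2-fold and 50 of 67 changed 4-fold, with 6 false calls, and 2 of 74, 24 of 64 and 58 of 62 sequences, with 1 false call. This baseline replaced pooled reads after recovery with these was seen to be low (12, 16 and 25 names and 1, 14 and 58 sequences). Of 20 lists tested, the 1 raised list was found and none of the others was called. In these simulations names varied independently with 1 common dispersion, lists were random and most names were unchanged. Members of measured lists were often correlated, with an estimate of 0.43 for let-7 and 0.93 for tRNA-Met. The simulation therefore does not bear on camera's calls at the preset correlation. Ping-pong overlaps, genomic windows and the mapping of 3′ ends need a genome and were left out. Lists of messenger RNAs and transposons were left out because the names could not be matched to them, as were alternatives on unannotated sequences and a split of snoRNAs by type.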

Results

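Small RNAs were sequenced from bovine oocytes at the germinal vesicle stage, the stage at which the oocyte is arrested in prophase of meiosis before it matures. There were 2 groups of 2 libraries: input RNA, and RNA recovered with an antibody against TDRKH. TDRKH is a tudor domain protein that binds PIWI proteins, and PIWIL3 is the PIWI protein named in the title of the study. PIWI proteins carry piRNAs, which arise from long single-stranded transcripts of genomic clusters. The design asks which small RNAs of the oocyte are recovered with TDRKH. The libraries hold no IP with a control antibody, so RNA held by TDRKH cannot be told apart from background of the IP. The read counts covered sequences of 18 to 36 nt with at least 1 annotation, so the totals are of annotated reads and not of the whole library. Input 1 held 1079364 listed reads, input 2 1354003, TDRKH IP 1 11138905 and TDRKH IP 2 11060320. These reads fell on 336526 and 377640 distinct sequences in the inputs and on 1328333 and 1354763 in the IPs. Replicates differed by more than counting error, with a chi-square per degree of freedom of 2.74 between inputs and 4.10 between IPs. The labels do not say that the replicates came from separate pools of oocytes, so p-values measure the spread between these samples, which may be technical.

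The TDRKH IP was composed almost wholly of reads from piRNA clusters, and nearly every other class of small RNA was depleted. Reads of piRNA clusters made up 96.8% ± 0.0484 of the IP and 88.3% ± 0.668 of the input (SD, n = 2 in every group mean given here). Bovine microRNAs, the short guides of Argonaute proteins, fell from 1.79% ± 0.0312 to 0.0669% ± 0.00934. The 5′ tRNA half-molecules, which end in the anticodon loop, fell from 1.27% ± 0.177 to 0.00453% ± 0.000528. Fragments of all tRNAs together made up 3.20% ± 0.235 of the input and 0.490% ± 0.0377 of the IP. Of the 15 classes tested, 14 passed an adjusted p of 0.05 with edgeR's quasi-likelihood test. The log2 change was 0.13 ± 0.01 (SE) for piRNA clusters (adjusted p = 8.51e-12), -4.75 ± 0.13 for bovine microRNAs (adjusted p = 7.92e-26) and -8.13 ± 0.18 for 5′ tRNA half-molecules (adjusted p = 5.83e-28). Fragments of mitochondrial rRNA fell by 6.25 on the log2 scale. Fragments of snoRNA fell by 2.38, of snRNA by 1.14 and of predicted protein-coding transcripts by 1.44, though the medians over their names turned positive with total microRNA reads as library size. Fragments of rRNA fell by 1.85, with a median over names that turned positive under TMM factors, DESeq2's size factors and total microRNA reads. So did the medians of 5′ and 3′ tRNA fragments shorter than half-molecules and of other tRNA fragments (0.995, 0.60 and 0.23 under TMM factors). The median of 3′ CCA fragments turned positive with total microRNA reads only. The class of other RNAs, which holds 7SK, 7SL and Y RNA, was at 0.349% ± 0.0474 and 0.374% ± 0.00525 and did not pass (adjusted p = 0.551). These are changes of share: an increase of piRNA cluster reads and a decrease of the rest cannot be separated from one another in such data.

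**Figure D1:**
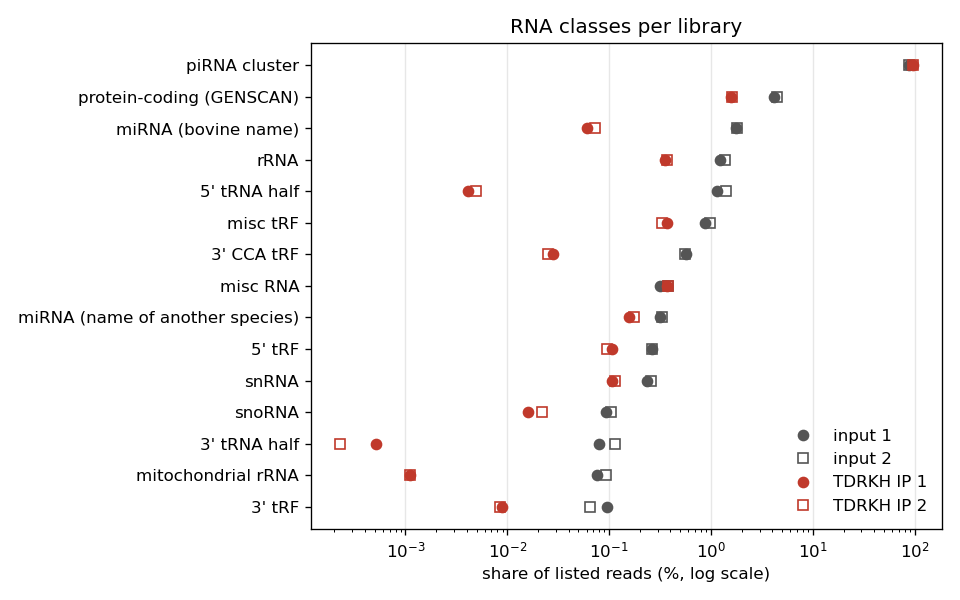
Share of listed reads (percent, log scale) of each of 15 RNA classes in each library, with inputs in grey and TDRKH IPs in red, filled circles for replicate 1 and open squares for replicate 2. The piRNA cluster class lies at 88.8% and 87.8% in the inputs and at 96.9% and 96.8% in the IPs, and the 5′ tRNA half-molecules at 1.15% or more and at 0.00416% and 0.00490%. The medians over names of 5′ half-molecules stayed negative under every scaling.

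Counted by name with listed reads as library size, more piRNA cluster names rose than fell and most names of other classes fell. Of 5414 names tested, 903 rose and 3153 fell at an adjusted p under 0.05. Among 1138 piRNA cluster names, 716 rose and 39 fell, with a median log2 change of 0.37, and 15 of those that rose and 17 of those that fell changed by 2-fold or more. With piRNA cluster reads as library size 482 of them rose and 53 fell (median 0.24), with TMM factors 1097 and 7 (1.71) and with DESeq2's size factors 1106 and 0 (2.51). Bovine microRNAs ran the other way, with 196 of 218 names fallen and 3 risen (median log2 change -5.84, or -5.75 with names at 0 in a group set to the bound that 3 counts allow). TMM factors gave 194 fallen and 19 risen, DESeq2's size factors 177 and 17, and total microRNA reads 110 and 28. The 3 that rose with listed reads were miR-12058 (log2 change 1.91), miR-2285cm (1.83) and miR-2285k-2 (1.27), named after their values were seen. Predicted protein-coding transcripts had 119 of 2964 names risen and 2252 fallen, with a median of -3.35 that turned to 1.35 with total microRNA reads as library size. The median over all names and the split of calls depended on the filter and on depth. With at least 10 RPM in 2 libraries the median was -0.13 (799 higher and 1083 lower), and with no filter 0.34 (273 and 2071). With thinned IPs, a step added later, it was -0.19 (727 and 1159). In the main fit the median was -2.44, and the split of calls depended on the scaling too. TMM factors moved that median by 1.33 and gave 1835 higher and 2552 lower names, DESeq2's size factors moved it by 2.11 and gave 1827 and 1339, and total microRNA reads moved it by 4.69 and gave 3279 and 512. The counts also fell with a library left out: 411 rose without input 1 and 417 without input 2, and 1739 fell without input 2, 1892 without TDRKH IP 1 and 1923 without TDRKH IP 2.

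The names with the most reads among those that rose were piRNA clusters. Each was higher in both IPs than in both inputs, as the rule for naming them required. The name on chromosome 6 from 110174004 to 110336024 rose from 144055 ± 745 to 162052 ± 1420 RPM, which are reads scaled to the listed reads of the library (log2 change 0.17 ± 0.03, adjusted p = 0.000953). Overlapping names on chromosome 23 from 13851174 to 14138004 and from 13905000 to 14137856 rose by a log2 change of 0.13 and 0.14. With piRNA cluster reads as library size, a scaling added later, the first of them turned to -0.01. The other and that on chromosome 6 kept their direction but not their call, with adjusted p between 1.16e-140 and 0.899 and between 7.76e-149 and 0.320 over all alternatives. Larger rises were seen on chromosome 3 from 90982081 to 91157012 (0.42 ± 0.04), on chromosome 13 from 77214012 to 77412030 (0.44 ± 0.04) and on chromosome 11 from 1348823 to 1354939 (0.51 ± 0.06). Names overlapping on chromosomes 14, 3 and 13 rose by between 0.22 and 0.39, and those of chromosomes 14 and 13 with the later start lost their call with single-name sequences (adjusted p of 0.210 and 0.148, the highest of their alternatives). The same name of chromosome 14 and that of chromosome 3 with the later start also lost it with piRNA cluster reads as library size. The genome build of these coordinates is not given in the sources used here, so genes within the clusters were not looked up.

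Some piRNA clusters fell in share. The cluster on chromosome 24 from 17793334 to 17800783 went from 8363 ± 1635 to 3434 ± 58.7 RPM (log2 change -1.28 ± 0.11, adjusted p = 5.68e-05). That on chromosome X from 73404001 to 73411298 went from 5980 to 2064 (log2 change -1.53 ± 0.07, adjusted p = 3.06e-06). Clusters on chromosome 2 from 59556283 to 59565020 (-0.69 ± 0.06) and on chromosome 19 from 63960001 to 63978019 (-0.64 ± 0.06) fell less. Clusters on chromosome 16 from 49598384 to 49603994 (-0.43 ± 0.08) and on chromosome 4 from 97000 to 103993 (-0.25 ± 0.08) passed with all libraries. Without input 1 their adjusted p was 0.159 and 0.144, and without input 2 0.106 and 0.414, the highest of any alternative for each being 0.159 and 0.414. The cluster on chromosome 4 was also at 0.0789 without TDRKH IP 2. With single-name sequences only, the cluster on chromosome 19 was at an adjusted p of 0.490, the highest of its alternatives. All 6 of these directions turned under DESeq2's size factors and total microRNA reads, and all but that on chromosome X under TMM factors.

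The files often name 1 cluster several times, and 1159 cluster names merged into 956 loci in a step added after the data were seen. Of 935 loci tested, 584 rose and 37 fell, with a median log2 change of 0.36. With piRNA cluster reads as library size, 393 rose and 49 fell. The 3 largest loci held 57.0% of all input reads and 59.5% of IP reads, which is 64.5% and 61.5% of the piRNA cluster reads. The largest, on chromosome 6, went from 304851 ± 4677 to 325043 ± 2185 RPM (adjusted p = 0.0317). The locus on chromosome 17 from 62734026 to 62887012 was at 153577 ± 703 and 148118 ± 845 and did not pass (adjusted p = 0.198). That on chromosome 23 rose from 111144 ± 352 to 121932 ± 172 (adjusted p = 0.00749). With piRNA cluster reads as library size neither of these rises held: the log2 change was -0.04 on chromosome 6 (adjusted p = 0.336) and 0.0005 on chromosome 23 (adjusted p = 0.991), and the locus on chromosome 17 fell by 0.19 (adjusted p = 0.00147).

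MicroRNA families fell with listed reads as library size. All 10 measured members of the let-7 list, which also held miR-98 and miR-202, fell, with a median log2 change of -5.50; let-7a went from 1534 ± 87.3 to 27.8 ± 8.80 RPM. All 9 measured members of the miR-17 to 92 list fell (median -6.42), miR-92a from 958 ± 62.1 to 13.6 ± 0.450. All 20 measured microRNAs known to be abundant in mammalian oocytes fell (median -6.62), among them miR-10a (-6.65), miR-30d (-6.74) and miR-92a (-6.14). The counts were the same adjusted over the list alone. Against the other names, these 3 lists passed camera with its preset correlation at adjusted p of 5.90e-19, 3.83e-07 and 1.83e-39. With an estimated correlation the adjusted p was 0.405 for let-7 and 0.403 for each of the others. These medians stayed negative under TMM factors and DESeq2's size factors, and with total microRNA reads as library size, which sets the class as a whole to no change, they were -0.77, -1.71 and -1.89. Under that scaling 6 members of let-7, 6 of miR-17 to 92 and 14 of the oocyte list fell, and 1 of miR-17 to 92 rose.

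Most measured microRNA markers of other cells fell in the IP. All 4 measured members of the cumulus and granulosa cell list fell: miR-21 (log2 change -7.02), which the oocyte list also holds, miR-503 (-7.16), miR-424 (-6.24) and miR-132, which had no reads in the IP and was named after its values were seen. Their median was -7.09, or -6.63 with the member at 0 set to its bound. That list passed camera at an adjusted p of 0.00104, with an adjusted p of 0.679 with an estimated correlation. Both measured leukocyte markers, miR-146b and miR-150, fell, as did both epithelial markers, miR-200c and miR-375, and the liver marker miR-122, from 385 ± 70.7 to 2.03 ± 0.456 RPM, and the medians of these lists stayed negative under every scaling. Of the smooth muscle and stromal markers, miR-143 fell (log2 change -5.74), and miR-1 was at 3.69 ± 5.22 and 1.58 ± 0.454 (adjusted p = 0.210), and the median of the list turned positive with total microRNA reads. None of the embryonic, erythroid and endothelial lists had a member with enough reads to test; their sums in the input were 0.369, 8.51 and 0.739 RPM. Lists with under 3 measured members were not tested as a set.

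Among tRNA fragments the half-molecules and the mitochondrial fragments fell most. All 134 names of 5′ half-molecules and all 31 of 3′ half-molecules fell, with medians of -7.98 and -8.71, or -7.42 and -6.98 with names at 0 in the IP set to their bound. Many of these names are copies of a tRNA gene that divide the same reads, so they are not independent. All 56 measured names of mitochondrial tRNA fell (median -7.32, or -7.09 with bounds), and their sum went from 9689 ± 269 to 51.7 ± 3.38 RPM. A 3′ CCA fragment of 1 mitochondrial tRNA had the smallest adjusted p of all names (log2 change -8.02 ± 0.08, adjusted p = 9.05e-09). The 5′ half-molecules of 2 names of tRNA-Lys (CTT) were at 82.3 ± 26.5 RPM in the input, had no reads in either IP and were at least 609-fold lower. The 3′ half-molecules of 2 names of tRNA-Glu (CTC) and a fragment of another mitochondrial tRNA, at 19.4 ± 1.36 RPM in the input, also had no IP reads. The mitochondrial list passed camera at an adjusted p of 5.15e-43, with an adjusted p of 0.246 with an estimated correlation. The medians of both kinds of half-molecules and of mitochondrial tRNA were negative under every scaling. With total microRNA reads as library size 9 of the 134 names of 5′ half-molecules and 8 of the 56 of mitochondrial tRNA did not pass, and with DESeq2's size factors 1 of the 134.

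Nuclear tRNA names went both ways, with 15 of 671 risen, 278 not past the threshold and the rest fallen, or 13 risen and 369 fallen adjusted over the list alone. DESeq2's size factors gave 195 risen and 264 fallen, total microRNA reads 405 and 174, and TMM factors 296 fallen and more risen than DESeq2. Their median of -1.46 turned positive under the first 2 of these. Camera gave an adjusted p of 2.32e-05, and of 0.679 with an estimated correlation. All 31 names of tRNA-Met fell (median -6.64), as did 24 of 27 of tRNA-Leu (-6.37, or -5.58 with bounds), 68 of 111 of tRNA-Val (-4.07), 62 of 81 of tRNA-Lys (-3.85), 48 of 78 of tRNA-Glu (-2.67) and 96 of 151 of tRNA-Gly (-1.38, with 5 risen, or 91 and 5 adjusted over the list alone). These 6 lists passed camera at adjusted p of 1.14e-05, 0.0113, 0.000248, 7.15e-13, 0.00128 and 3.13e-09 in this order, each with an adjusted p of 0.679 with an estimated correlation, or 0.715 for tRNA-Glu. The medians of tRNA-Met and tRNA-Leu were negative under every scaling, with 22 names of tRNA-Met fallen under DESeq2's size factors and total microRNA reads, and 21 of tRNA-Leu fallen and 3 risen under the first and 15 and 6 under the second. The medians of tRNA-Val, tRNA-Lys and tRNA-Glu turned with total microRNA reads, and that of tRNA-Gly with DESeq2's size factors also. Under TMM factors 38 names of tRNA-Gly rose and 61 fell, of tRNA-Lys 19 and 54, of tRNA-Glu 14 and 39 and of tRNA-Val 8 and 65. With the replicate number as a block tRNA-Leu lost its camera call (adjusted p = 0.0671). The nuclear tRNA name with the most reads, a fragment of tRNA-Gly (TCC), was at 1983 ± 287 and 1886 ± 186 RPM (log2 change -0.07, adjusted p = 0.530).

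Fragments named for tRNA-Cys lay above the other names, with 7 of 61 risen and none fallen (median 0.98). Adjusted over the list alone none passed edgeR's test, 9 had an unadjusted p under 0.05, and DESeq2 with its size factors called 53. Of 24 names of tRNA-Arg (median 0.59), none rose and 1, a 3′ CCA fragment with anticodon TCG, fell, which also had the only unadjusted p under 0.05 and did not pass adjusted over the list alone, while DESeq2 called 10 as higher. Both lists passed camera upward, at adjusted p of 1.14e-05 and 0.0105, with tRNA-Arg losing its call under TMM factors (adjusted p = 0.375). Both had an adjusted p of 0.679 with an estimated correlation, and both medians were positive under every scaling. Among tRNA-Asp names 27 of 42 fell, among tRNA-Gln 4 of 28, among tRNA-Tyr 9 of 9 and among tRNA-Trp 1 of 13, with camera adjusted p of 0.158, 0.275, 0.750 and 0.0729. Adjusted over the list alone 26 names of tRNA-Asp fell. The medians of tRNA-Asp, tRNA-Gln and tRNA-Ala turned positive under TMM factors, DESeq2's size factors and total microRNA reads, and those of tRNA-Tyr, tRNA-Thr and tRNA-SeC under the last alone. No tRNA-Tyr name passed under TMM factors or DESeq2's size factors. Under TMM factors 13 names of tRNA-Asp rose and 14 fell, of tRNA-Gln 18 and 4 and of tRNA-Trp 9 and 1. Measured were 3 names each of tRNA-Ala, tRNA-Ser and tRNA-Thr, of which 2, 1 and 2 fell and 0, 1 and 1 rose (camera adjusted p = 0.926, 0.410 and 0.666). For tRNA-Thr the median was -2.93 and the mean 0.51, and for tRNA-Ser 0.72 and -0.30. The risen tRNA-Thr name, a 3′ CCA fragment with anticodon CGT, had no input reads, was at 3.33 ± 0.272 RPM in the IP and was at least 2.70-fold higher; without input 2 its adjusted p was 0.0613. Both tRNA-SeC names fell, the single name of undetermined type rose, and the 1 tRNA-Asn and 2 suppressor tRNA names did not pass. Under TMM factors the tRNA-Asn name (log2 change 1.25) and both suppressor names (median 1.74) rose. DESeq2's size factors called both suppressor names as higher but not that of tRNA-Asn. No name of tRNA-His, tRNA-Ile, tRNA-Phe or tRNA-Pro had enough reads to test.

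Among structural RNAs, Y RNA and 7SL fell and 7SK did not. All 8 names of Y RNA, small RNAs bound by the Ro protein, fell (median -5.06, adjusted p = 3.06e-07 with camera and 0.618 with an estimated correlation), from a sum of 770 ± 124 to 21.7 ± 4.89 RPM. Of 12 names of 7SL, the RNA of the signal recognition particle, 11 fell (median -5.50, adjusted p = 0.00198, and 0.679 with an estimated correlation). Of 20 names of 7SK, an RNA that binds the P-TEFb elongation factor, 9 rose and 3 fell. Its median was 0.48, its mean -0.37 and camera's direction upward (adjusted p = 0.00716, and 0.679 with an estimated correlation). The 7SK names summed to 2494 ± 341 in the input and 3712 ± 47.3 RPM in the IP. Over the 9 risen names, 46.1% to 99.9% of reads, pooled over all libraries, had a first T. In the class of other RNAs, which also holds 7SL and Y RNA, that share rose from 64.95% ± 0.721 to 86.3% ± 1.55. Reads of 24 to 27 nt rose from 54.4% ± 0.224 to 63.8% ± 1.18 of that class. Whether the reads of risen 7SK names come from 7SK RNA or from other loci of similar sequence was not tested. The 1 name of RNase P RNA fell, from 5.28 ± 4.33 to 0.315 ± 0.0621, a direction that turned with total microRNA reads, and those of RNase MRP and vault RNA had too few reads to test. The medians of Y RNA and 7SL were negative, and that of 7SK positive, under every scaling, but with total microRNA reads only 2 of 8 names of Y RNA fell, and none of 7SL with 1 risen. For 7SK, TMM factors and DESeq2's size factors gave 16 risen and 3 fallen, and total microRNA reads 17 and 0.

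Fragments of spliceosomal RNAs mostly fell. For U1, 27 of 28 names fell (median -4.10, adjusted p = 6.09e-05 with camera and 0.679 with an estimated correlation), for U2 18 of 25, for U4 2 of 3 and for U5 2 of 6. The names that rose were 1 of U1 (log2 change 0.34), 4 of U2, 1 of U4 (1.07) and 1 of U5 (1.03), looked at after their values were seen; the files give such copies identifiers without symbols. The U12 name fell by 6.66 on the log2 scale, and U11 had too few reads. Of 7 U6 names 4 rose and 3 fell, with a median of 0.64 and a mean of -1.73. The lists of U2, U4, U5 and U6 did not pass camera (adjusted p = 0.121, 0.666, 0.361 and 0.140). Of 78 snoRNA names 68 fell and 1 rose (median -2.88), or 69 and 1 adjusted over the list alone, and the list did not pass camera against the other names (adjusted p = 0.385). TMM factors gave 50 fallen and 3 risen, DESeq2's size factors 12 and 3, and total microRNA reads 1 and 53. DESeq2's size factors gave 7 fallen and 7 risen for U2. With total microRNA reads as library size no name of U1 or U2 fell and 2 and 19 rose. Under that scaling the medians of U1, U2 and snoRNA turned positive, those of U4, U12 and U6 kept their sign under every scaling, and that of U5 also turned under TMM factors and DESeq2's size factors.

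All 5 names of 18S rRNA fell (median -2.35, adjusted p = 7.81e-13 with camera and 0.472 with an estimated correlation), from a sum of 10773 ± 763 to 2171 ± 5.69 RPM. The 2 with the most reads had log2 changes of -2.44 ± 0.06 and -2.29 ± 0.06, both turning positive with total microRNA reads. The second of them lost its call with DESeq2's size factors (log2 change -0.15, adjusted p = 0.174). Both mitochondrial rRNA names fell (median -5.96), from 850 ± 127 to 11.2 ± 0.0715 RPM in sum. Of 39 names of 5S rRNA 24 fell and 2 rose (median -1.08, camera adjusted p = 0.354), the risen ones by log2 changes of 1.59 and 2.99, and of 9 names of 5.8S rRNA 1 fell and 1 rose (median -0.19, camera adjusted p = 0.354), with none risen adjusted over the list alone. The medians of 18S, 5S and 5.8S turned positive with total microRNA reads, and those of 5S and 5.8S under TMM factors and DESeq2's size factors also. Under TMM factors 17 names of 5S rose and 17 fell, and 8 and 1 of 5.8S. In all, 19 of the 33 lists tested passed camera with the preset correlation. With an estimated one none passed, and 4 had an unadjusted p under 0.05: let-7, miR-17 to 92, oocyte microRNAs and mitochondrial tRNA. The estimate was 0.0243 for mitochondrial tRNA and -0.0467 for miR-17 to 92, near or below the preset correlation of 0.01. The loss of a call with the estimated correlation therefore does not by itself show that members were correlated. Camera sets a list against the other names, and the lists of tRNA-Ala, tRNA-Gln, tRNA-Thr, tRNA-Tyr, U5 and 5.8S rRNA had an upward direction beside negative medians. Counts adjusted over the list alone are given where they differed.

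Among the names with the largest rise were 4 predicted protein-coding transcripts with no reads in the inputs. The files do not pair their identifiers with gene symbols. GENSCAN00000042865 was at 4.28 ± 0.297 RPM in the IP and at least 3.47-fold higher, and GENSCAN00000012600 at 4.01 ± 0.466 and at least 3.25-fold higher. The call on the latter was lost without input 1 (adjusted p = 0.0554) or input 2 (adjusted p = 0.0671). Of the other 2, 1 lost its call without input 1 (adjusted p = 0.135) or input 2 (adjusted p = 0.156) and the other without input 2 (adjusted p = 0.0516). All 4 had an adjusted p above 0.05 with no filter, up to 0.209. Names of microRNAs of other species went both ways, with 26 of 119 risen and 54 fallen (median -0.81, which turned positive under TMM factors, DESeq2's size factors and total microRNA reads).

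Single sequences gave a different balance, with more risen than fallen. Of 11786 sequences with at least 10 RPM in 2 libraries, 4943 rose and 2340 fell, and 11025 were from piRNA clusters. Of those, 4791 rose and 1870 fell (median log2 change 0.73). Of 159 bovine microRNA sequences 158 fell, and all 56 sequences named only as 5′ tRNA half-molecules fell. Of 113 sequences of predicted protein-coding transcripts 70 rose and 11 fell (median 0.99), whereas of their names 119 rose and 2252 fell. Of 60 sequences of other RNAs 28 rose and 6 fell (median 0.90), and of 27 of snRNA 11 and 12 (0.52). Sequences that rose were 96.9% from piRNA clusters, 89.7% began with T and 18.7% were 18 to 22 nt long; for sequences that fell the shares were 79.9%, 77.9% and 11.4%, and for those that did not pass 96.9%, 89.2% and 11.1%. TMM factors moved the median over sequences by -0.67 and gave 667 higher and 2727 lower, DESeq2's size factors moved it by -0.65 and gave 198 and 2615, and total microRNA reads moved it by 4.75 and gave 11243 and 380. With the main scaling, 1809 rose without TDRKH IP 1 and 1167 without TDRKH IP 2.

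Of the sequences with the most reads in both groups, 3 from piRNA clusters were lower in both IPs than in both inputs. TCTGACATCGGTTGCTCTGCTTCAAT, of the cluster on chromosome 17, went from 8860 ± 243 to 3677 ± 96.4 RPM (log2 change -1.27 ± 0.20, adjusted p = 2.49e-06). TCGAATTGTGGTGTTGGAGAAGACTT, of the cluster on chromosome 16 and 2 others, went from 5304 ± 134 to 2665 ± 380 (-0.99 ± 0.20), with an adjusted p of 0.0511 without TDRKH IP 2. TTCTTGGGAATTGTGATGAGGGTT, of the chromosome 23 cluster, went from 4674 ± 301 to 2336 ± 159 (adjusted p = 0.000116). These 3 turned positive with total microRNA reads as library size.

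Reads of both groups peaked at 26 nt, and the groups differed beside this peak and at the long end of the range. Of 19 lengths 10 passed: reads of 23, 24, 27 and 28 nt were a larger share of the IP, and those of 31 to 36 nt a smaller one. Reads of 33 to 36 nt made up 2.52% ± 0.403 of the input and 0.501% ± 0.0457 of the IP, and reads of 28 nt rose by a log2 change of 0.20 ± 0.05 (adjusted p = 0.00113). Only 6 lengths passed without input 1 and 6 without input 2. Among piRNA cluster reads alone, a comparison added later, 7 lengths passed. Each length from 18 to 22 nt and 28 nt rose, and 26 nt fell by a log2 change of -0.20 ± 0.03 (adjusted p = 4.65e-07). The share of 18 to 22 nt among piRNA cluster reads was 10.9% and 11.1% in the inputs and 13.1% and 14.2% in the IPs. Over all reads that share was 14.4% ± 0.117 and 14.6% ± 0.828, with IP replicates on both sides of the inputs. The mean read length was 25.2 nt ± 0.0537 in the input, and the IP minus input difference was -0.243 nt.

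**Figure D2:**
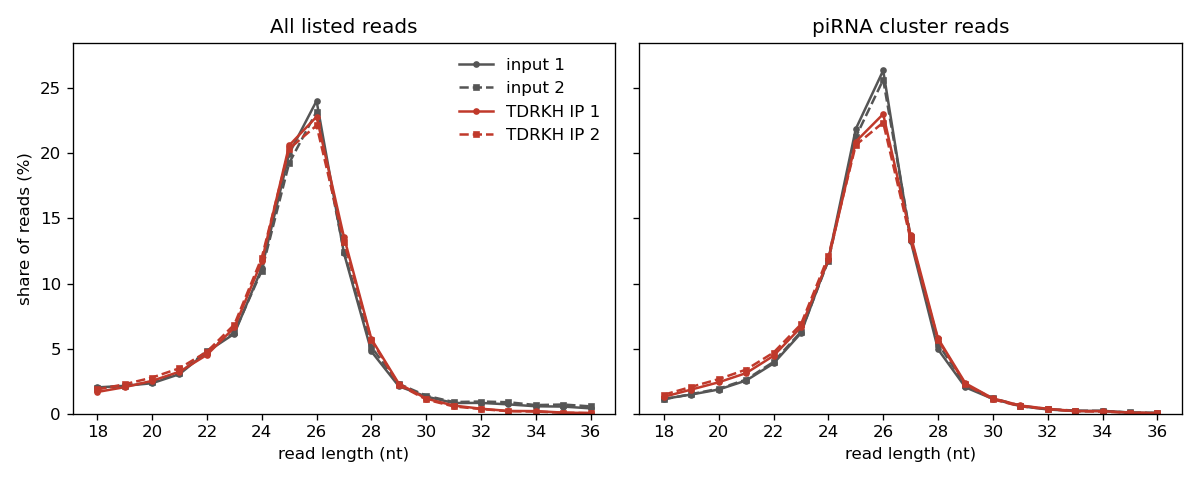
Share of reads (percent) at each length from 18 to 36 nt for all listed reads (left) and for piRNA cluster reads (right), with inputs in grey and TDRKH IPs in red, solid lines for replicate 1 and dashed lines for replicate 2. Every library peaks at 26 nt, and among piRNA cluster reads that peak is at 26.4% and 25.7% in the inputs and at a mean of 22.7% in the IPs.

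A first T, the base that stands for the 5′ U of primary piRNAs, was more frequent in the IP. It began 82.5% ± 0.160 of input reads and 87.8% ± 0.583 of IP reads. For no single share can the exact permutation test of 2 against 2 libraries give a p under 0.333, and this is the p here and of the shares below where the replicates of the groups did not overlap. Within reads of 18 to 22 nt, which include the microRNAs, the share was 73.8% ± 0.654 and 88.1% ± 0.817. Among piRNA cluster reads alone it was 88.1% ± 0.573 and 88.2% ± 0.567, with overlapping replicates. Over all reads, with each distinct sequence counted once, the share was 70.8% ± 1.28 and 70.7% ± 0.620. The Wilson 95% interval of 1 library was narrow, 82.3% to 82.5% for input 1 and 88.2% for both bounds of TDRKH IP 1. Intervals and floors cover counting error only, since PCR copies were counted as reads.

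An A at position 10, the mark of secondary piRNAs of the ping-pong cycle, was found in 39.9% ± 0.174 of input reads and 42.2% ± 0.441 of IP reads of 18 to 32 nt. Among piRNA cluster reads alone the shares were 40.9% ± 0.122 and 42.0% ± 0.432. The rise was not limited to this position: over piRNA cluster reads of all lengths A rose by 1.04 percentage points at position 10, 2.10 at position 6 and 2.55 at position 8. Over all reads of 18 to 32 nt, with each distinct sequence counted once, the shares with A at position 10 were 35.8% ± 0.801 and 33.9% ± 0.0667, the opposite direction. Distinct sequences depend on depth and on sequencing errors, and these shares were not computed with thinned IPs. In reads of 23 to 25 nt the shares were 43.3% ± 0.551 and 43.4% ± 0.568, with overlapping replicates.

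More IP reads looked like a more abundant sequence of the same library with 1 A added at the 3′ end. Such reads made up 9.36% ± 0.731 of the input and 15.1% ± 0.0490 of the IP, and those with 1 base of any kind added 18.8% ± 1.37 and 27.5% ± 0.123. Deeper libraries hold more of the shorter forms that this measure needs, and the IPs were the deeper ones. The share of A among the added bases was 49.9% ± 0.247 and 55.0% ± 0.0680. In a measure added later, the last base of piRNA cluster reads was compared with the base that longer reads, pooled over all libraries, carry there. Of the reads with such a base to compare, which were 47.7% ± 2.59 and 54.0% ± 0.165 of piRNA cluster reads, the last base was an A that differed in 8.69% ± 0.210 of the input and 9.62% ± 0.00587 of the IP, and any base that differed in 11.5% ± 0.101 and 11.6% ± 0.0649. At the position 4 bases before the last, an A differed in 0.678% ± 0.145 and 0.263% ± 0.000454. Most listed reads were of the IPs, so input reads were compared mainly with IP reads in this measure. Without a genome, whether an added A was templated was not analysed here.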

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

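Tests chosen only after the results were seen were those with piRNA cluster reads as library size or alone, thinned IPs, merged names, the last base against longer reads and exact microRNA names. The cause of a change was not tested unless stated.

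Among 903 names higher and 3153 lower, TMM factors gave 1835 higher, total microRNA reads 3279 and 512 lower, DESeq2 with its size factors 1827 and 1339, and DESeq2 with total reads 576 higher. With no filter, which adjusts over 29507 names, 273 were higher and 2071 lower; with at least 10 RPM, which leaves 2308 names, 1083 were lower; with single-name sequences 329 were higher; with thinned IPs, which leave 2450 names, 1159 were lower. Leaving out 1 library gave 411 to 683 higher and 1739 to 2151 lower. Among 4943 sequences higher and 2340 lower, TMM factors gave 667 higher, DESeq2 198 and total microRNA reads 11243 and 380 lower. A filter of 1 RPM, which keeps 94522 sequences, gave 9827 and 18497, and 100 RPM, which keeps 1167, gave 541 and 108. Leaving out 1 library gave 1167 to 4882 higher and 2149 to 2328 lower.

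Of 15 RNA classes 14 passed in every leave-one-out fit. Of 19 read lengths 10 passed, and 6 to 9 with 1 library left out. Of 33 lists 19 passed camera, 0 with an estimated correlation and 18 with TMM factors, where tRNA-Arg was lost (adjusted p = 0.375).

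IP minus input differences of shares, in percentage points, depended on the counting. Counts of distinct sequences also depend on depth, and those below were not repeated with thinned IPs. With each distinct sequence counted once, the first T went from 5.25 to -0.0410, A at position 10 from 2.28 to -1.98, reads of 18 to 22 nt from 0.188 to 2.98, and an added 3′ A from 5.74 to 4.80; the mean length difference went from -0.243 nt to -0.503 nt. By length, A at position 10 turned to -1.56 at 18 to 22 nt, -2.53 at 23 to 25 nt (-0.446 among reads without a first T) and -1.53 at 26 to 32 nt, and the first T to -5.44 at 23 to 25 nt and -1.79 at 26 to 32 nt. Without sequences seen once, the first T was at 3.66 and A at position 10 at 1.83, or -0.996 at 23 to 25 nt. Without the 10 most abundant sequences, A at position 10 was at 1.89, reads of 18 to 22 nt at -0.0324 and of 26 to 32 nt at 0.0497. Among piRNA cluster reads only, the first T was at 0.0939 (-0.636 at 26 to 32 nt), A at position 10 at 1.03 (-0.591 at 23 to 25 nt, -0.482 without a first T), reads of 18 to 22 nt at 2.69, of 23 to 25 nt at -0.133 and of 24 to 27 nt at -3.87, and the mean length at -0.151 nt. The last base measure of 3′ A gave 0.927. Leaving out 1 library gave -0.397 to 0.773 for reads of 18 to 22 nt (negative without TDRKH IP 2), -1.01 to 0.341 for 26 to 32 nt (positive without TDRKH IP 2) and -0.299 to 0.504 for A at position 10 at 23 to 25 nt (negative without input 2 or TDRKH IP 1).

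Log2 changes of named items turned mostly with total microRNA reads, which raises all of them. They were then 3.48 for the cluster on chromosome 24, 3.23 for X, 4.08 for 2, 4.34 for 16, 4.53 for 4 and 4.13 for 19, 2.32 and 2.47 for the 18S rRNA names, and 3.49, 3.76, 3.78, 4.11 and 4.39 (in order of size) for the 5 most abundant sequences. TMM factors gave 0.0547, 0.650, 0.912, 1.096 and 0.703 for the clusters on chromosomes 24, 2, 16, 4 and 19. DESeq2's size factors gave 0.84, 0.60, 1.45, 1.71, 1.90 and 1.501 for those on chromosomes 24, X, 2, 16, 4 and 19. With piRNA cluster reads as library size, the first name on chromosome 23 was at -0.00596. Of the settings tried on named items, 391 kept direction and call, 31 lost the call, 5 gained it and 25 reversed.

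The replicate numbers are not known to pair an input with an IP; the difference between inputs 1 and 2 and that between IPs 1 and 2, which pairing would link, correlated at 0.0199 over names. With the number as a block, 862 names were higher and 3091 lower, 4410 sequences higher and 2313 lower, 11 lengths, 14 classes and 18 lists passed, with tRNA-Leu at an adjusted p of 0.0671.

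Not run, for want of a genome or of unannotated sequences, were the alternatives on unannotated sequences only, on ping-pong overlaps, on genomic windows and on the removal of 1 to 3 nt. Depth limits names with few input reads, since the IPs were sequenced deeper.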

Other observations

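Of the tests below, that of the first T over risen names was chosen only after the result was seen; the piRNA cluster measures and the test of depth were also added after the data were seen.

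The share of 18 to 22 nt among piRNA cluster reads was higher in the IP. Short reads that are the start of a listed sequence of 24 nt or more rose from 8.26% ± 0.480 to 11.5% ± 0.617 of piRNA cluster reads, and other short reads were at 2.72% ± 0.300 and 2.15% ± 0.179. The starts of longer sequences carried 121% of the difference, or 111% when only longer sequences of the inputs counted. A 3′ shortening of longer piRNAs recovered with TDRKH, in the cell or during the IP, may explain these values. Depth as the source of these starts is argued against. With IPs thinned to 1079364 reads and only longer sequences of the same library counted, starts were at 7.24% ± 0.584 and 10.5% ± 0.468. That is 121% of the difference in share between the inputs and the thinned IPs. Starts already made up most short reads of the inputs, so a rise of short reads of any kind would mostly fall on them. A short read that differs by a base is not counted as a start. At the position 4 bases before the last, 2.33% ± 0.499 of input and 0.967% ± 0.0152 of IP reads compared with longer ones differed. This may raise the percentages carried by starts. Whether shortening occurred before or after lysis, and a separate class of short piRNAs with the same 5′ ends, stay open.

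Outside the piRNA clusters 187 names rose. The median share of reads with a first T was 92.9% over these and 29.5% over names that fell, against 88.7% over piRNA cluster names. Over the 975 names outside the clusters that did not pass it was 82.4%, so a frequent first T was not particular to risen names. These shares, and the lengths below, pool the reads of all libraries, so the deeper IPs weigh most in them. The mean length of the reads of a name had a median of 21.6 nt over the risen names, below the quartiles of 24.4 nt and 25.2 nt over piRNA cluster names. That piRNA-like reads carry the names of other RNAs would explain the first T but not this length, so it stays open. By library and class, the first T rose from 36.4% ± 0.285 to 77.5% ± 0.652 of reads of predicted protein-coding transcripts. Their reads of 24 to 27 nt rose from 27.7% ± 1.82 to 45.4% ± 1.94. For 5′ half-molecules the first T was at 14.5% ± 2.47 and 14.1% ± 2.03. Among 3′ CCA fragments, reads of 24 to 27 nt fell from 1.49% ± 0.387 to 0.370% ± 0.0615. These class shares cover all names of a class, not the risen ones alone. With sequences of a single name, 158 of the 187 risen names were tested again, and 79.7% of the 158 were higher. For the names higher again, that argues against reads shared between several names as the source. Such sharing stays open for the other risen names, which include those not tested again. No listed sequence had both a piRNA cluster name and a name of another class. Sharing with piRNA clusters was therefore not tested. Whether the reads of risen names arise from the named genes or from other loci of similar sequence stays open, and of the 3 risen bovine microRNAs miR-2285k-2 had a first T in only 9.31% of reads.

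The 5 most abundant sequences took a smaller share of the IP. As a share of piRNA cluster reads of 24 to 28 nt they went from 3.82% ± 0.0321 to 1.92% ± 0.0926, a change of -49.6%. That argues against growth of other RNA classes or of shorter reads as the source. The outcome could be foreseen from other values. Classes other than piRNA clusters together fell from 11.7% ± 0.668 to 3.18% ± 0.0484 of listed reads. Reads of 18 to 22 nt rose by only 2.69 percentage points of piRNA cluster reads. Other trimmed or extended forms of the 5 sequences were not counted with them. Loss of their own reads to such forms was therefore not tested. The 100 most abundant sequences of each library held 15.4% ± 0.827 of piRNA cluster reads in the input, with an IP minus input difference of -3.37 percentage points, the 1000 most abundant 34.2% ± 2.68 and 34.6% ± 1.35, and the 10000 most abundant 55.0% ± 2.77 and 60.0% ± 1.17, the opposite direction. A weaker binding of these sequences to the complex may explain this, as may a bias of library preparation that differed with the amount of RNA; neither was tested.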
